A study of Homo sapiens with 44 samples.

How the data were processed

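Total RNA had been extracted from frozen specimens of head and neck squamous cell carcinoma and of normal mucosa, labelled with biotin as cRNA and hybridised to Affymetrix U95 arrays, per the labels' protocols. Each array carries sets of short oligonucleotide probes, and 1 value summarises the probes of a set. The deposited values were intensities on a linear scale, 1 per probe set and array, for 44 arrays. MAS5 and RMA are named in the submitters' processing notes, with no role or order. Which of them made the values, and with what background correction and normalization, is not given in the sources used here. The values themselves were all positive, from at least 8.49 to at most 20630, with array medians of 83.7 to 93.2, lower quartiles of 31.5 to 36.4 and upper quartiles of 209 to 224. Such nearly shared quartiles mean that the values had been scaled between arrays before deposit, so a change in total messenger RNA per cell could not be seen. Every table column was assigned to a sample, and no scanner file was used here.

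Groups came from the sample titles and source names, which give the tissue and a number from 1 to 22. The free-text description and treatment fields call every sample normal, so they were not used for the groups. The series design states that both tissues came from each of 22 patients, and titles with the same number were taken as a pair. Before any test, deviations from the tissue means correlated at 0.402 on average for arrays with the same number (0.0053 to 0.863, over 0.1 in 20 of 22 pairs) and at -0.0168 for different numbers. Of the 22 arrays of each tissue, 9 normal and 9 cancer arrays correlated best with the array of their own number. In sex-linked transcripts, 0 of 22 pairs were mismatched. The pairing therefore rests on the stated shared patient. The highest correlation between any arrays was 0.988, so no array was treated as a duplicate.

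Probe sets were named through the platform annotation that was given, with symbols updated through gene IDs from the RefSeq annotation. Of 12625 probe sets, 10961 had 1 gene, 545 several and 1119 none there. Of the 1-gene IDs, 10949 matched. Probe sets with several genes were tested but not named. The 67 control probe sets of the manufacturer and 28 probe sets of XIST and Y-linked genes were left out, which left 12530 tested and 8210 genes. No coordinates are given, since the files name no genome build. The series text and the annotation name different versions of the U95 array.

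Intensities were taken as log2 with no offset. limma 3.58.1 in R 4.3.3 fitted patient and tissue to each probe set (lmFit, eBayes) over all 44 arrays, and p-values were adjusted by the Benjamini-Hochberg method over 12530 probe sets, with a threshold of 0.05. The ± of a difference is the moderated standard error. A fold is 2 to the power of the log2 difference. Before the data were examined, the design, 26 gene lists, the alternatives and a rule for named genes were fixed. Genes were named if they were among the 12 largest rises or the 12 largest falls with an adjusted p under 0.05, 1 gene symbol and the same direction in at least 18 of 22 pairs, or among the 3 largest differences in size of a list, called or not. Some of these meet both parts of the rule.

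In the lists, a gene was measured by its probe set of highest mean over the 44 arrays. The lists were squamous differentiation, squamous protease inhibitors, basal and stress keratinocyte, matrix and matricellular, matrix proteases and plasminogen system, cell cycle, interferon response, chemokines and inflammatory mediators, hypoxia and glycolysis, drug, alcohol and retinoid metabolism, the EGFR family, amplicon genes, mesenchymal transition, immediate early and heat shock, oxidative phosphorylation, and markers of skeletal muscle, salivary gland, T and NK cells, B and plasma cells, macrophages and dendritic cells, neutrophils, mast cells, endothelium, smooth muscle, adipocytes, and red cells with melanocytes and Schwann cells. Each list was tested by camera with a preset correlation of 0.01 and with an estimated one, and by fry, all adjusted over the 26 lists. Calls of single genes are given over all probe sets and adjusted over the list alone.

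The procedure was tested on simulated data for 22 pairs and 12530 probe sets, with the residual spread of the real ones and 200 probe sets changed. It recovered 86% of those changed by 0.5 and 98% of those changed by 1 on the log2 scale, with 4.17% of calls false and 0 of 25 unchanged lists called. Noise was drawn independently for each probe set, and the simulated lists held random genes. The real lists had estimated correlations of 0.072 to 0.63, so the simulation says nothing about false calls among them. The alternatives were the fit without the patient block, the patient as a random block (lists by cameraPR on its moderated t), a trended and robust variance, array weights, quantile normalization, subtraction of array medians, filters that dropped the dimmest probe sets, an offset of 64, a floor of 20, a Wilcoxon signed-rank test and a paired t-test on 22 pairs, 1 probe set per gene, covariates for muscle, salivary tissue and the 3' to 5' signal ratio, lists without shared members, and each pair left out. After seeing the data, 2 kinds were added: the 11 pairs with the higher and the 11 with the lower mean log2 level of bacterial control probe sets, and leaving out pairs 11 and 21, which held an array with a log2 beta-actin 3' to 5' ratio above 1. Correlations over pairs have permutation p-values from 100000 resamples, and all tests were two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.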

Results

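The series measured messenger RNA levels in head and neck squamous cell carcinoma, a cancer of the mucosal lining of the mouth and throat, and in normal head and neck mucosa. Each of 22 patients gave a cancer specimen and a normal specimen, so 44 Affymetrix U95 arrays formed 22 pairs. The question was which genes differed in expression between the cancer and the paired normal tissue. Each array held 12625 probe sets, and 12530 of them were tested. The arrays had nearly shared distributions, with medians of 83.7 to 93.2 intensity units. The number of arrays limits the precision of every value. Differences are log2 cancer minus normal mucosa, and ± stands for the standard error from the paired limma fit over 22 pairs.

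The first principal component held 30.1% of the variance and varied mainly between patients: its scores in the paired specimens correlated at r = 0.938. The second held 13.1% and placed cancer and normal mucosa in the same order in 22 of 22 pairs. The first component followed the level of bacterial control probe sets, which human RNA is not meant to label (Pearson r = 0.876 over pair means, Spearman rho = 0.868, permutation p = 1e-05 for both, the smallest that the resamples can give). Benjamini-Hochberg adjustment over the 3 technical relations computed gave 3e-05 for each, and r was 0.846 without the 2 pairs farthest in the first component. It was 0.559 within the 11 pairs with the higher control level and 0.908 within the 11 with the lower level. The comparison was therefore repeated in each of these subsets, called here higher-control and lower-control pairs and chosen after seeing the data. Their counts and list medians stand beside the pooled ones, with subset values for only a few single genes. The control level itself differed by -0.00978 ± 0.256 (SD, n = 22 pairs) between the tissues.

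**Figure D1:**
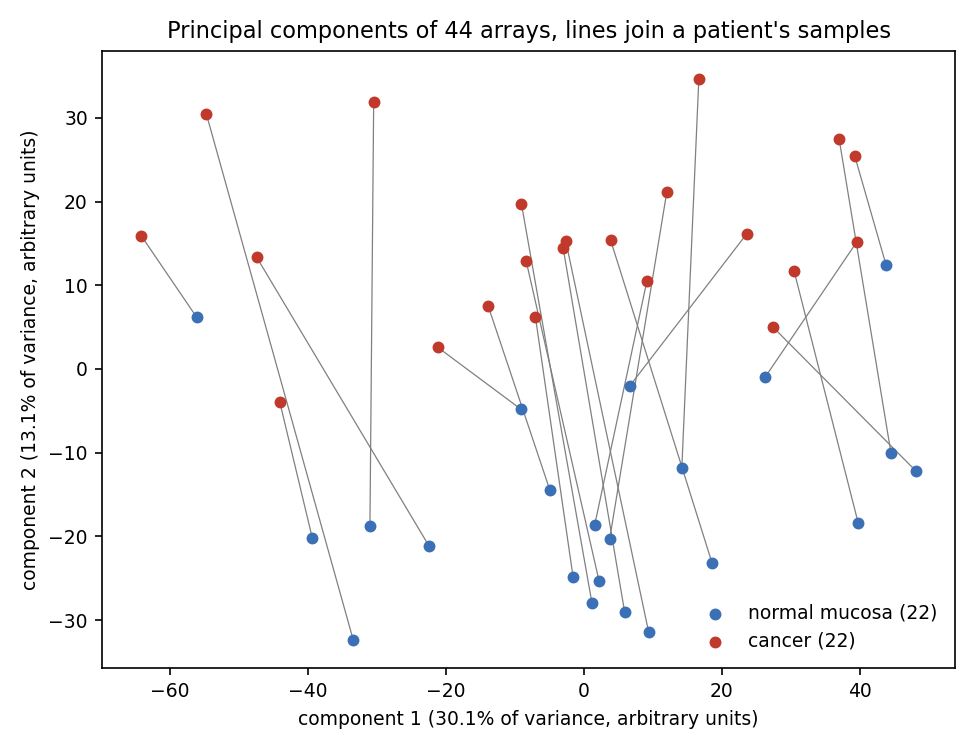
Scores of the 44 arrays on the first component (horizontal axis, 30.1% of variance) and the second (vertical axis, 13.1%), in arbitrary units. Each point is 1 array and each line joins the normal mucosa and the cancer of 1 patient. Cancer lies above normal mucosa on the second component in 22 of 22 pairs.

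Genes of the surface layers of squamous epithelium fell most in cancer, and genes of the connective tissue matrix and the enzymes that cut it rose most. KRT4, a keratin of the upper layers of mucosa, fell from a mean intensity of 11468 to 776, a log2 difference of -3.89 ± 0.30 (probe set 39657_at, 14.8-fold lower, adjusted p = 2.36e-08). TGM3, a transglutaminase of the cornified envelope, differed by -3.61 ± 0.33, MAL, a membrane trafficking protein, by -3.57 ± 0.25, and KRT13, the partner keratin of KRT4, by -2.74 ± 0.40. Each of these 4 genes was lower in cancer in 22 of 22 pairs. MMP1, an interstitial collagenase, rose from 37.3 to 341, a log2 difference of 3.19 ± 0.52 (probe set 38428_at, 9.13-fold higher, adjusted p = 0.000147, higher in 20 of 22 pairs). SPP1, the secreted phosphoprotein osteopontin, rose by 2.91 ± 0.32 (adjusted p = 3.95e-06, higher in 21 of 22 pairs).

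Among called genes that changed the same way in at least 18 of 22 pairs, the rest of the 12 largest rises were those of COL1A2 (2.30 ± 0.31), FN1 (2.23 ± 0.33), MMP12 (2.04 ± 0.35), POSTN (1.95 ± 0.29), TGFBI (1.84 ± 0.31), FAP (1.77 ± 0.28), MMP9 (1.75 ± 0.23), COL3A1 (1.75 ± 0.29), ITGA6 (1.75 ± 0.30) and PLAU (1.74 ± 0.28). COL1A2 and COL3A1 encode fibrillar collagens, FN1 fibronectin, FAP a protease of activated fibroblasts, and PLAU the urokinase plasminogen activator. POSTN, which encodes the matrix protein periostin, was higher in cancer in 22 of 22 pairs. The other large falls were those of ENDOU (-2.35 ± 0.26), EMP1 (-2.33 ± 0.24), HOPX (-2.30 ± 0.31), ADH7 (-2.30 ± 0.41), SLURP1 (-2.28 ± 0.29), CRISP3 (-2.23 ± 0.35), MYL1 (-2.20 ± 0.72) and KLK13 (-2.09 ± 0.22). ADH7 is an alcohol dehydrogenase of the upper digestive tract, KLK13 a secreted kallikrein protease, and MYL1 a myosin light chain of fast skeletal muscle. Adjusted p over these 24 genes lay between 6.73e-09 for MAL and 0.029 for MYL1. A further probe set of COL1A2 and one of MYL1 were not called, and no other probe set of the 24 genes was called in the opposite direction. CRISP3 had a cancer mean of 4.51, no higher than the 4.54 of the bacterial control probe sets there, and 10 of 22 cancer arrays lay above their own control level. With dimmer cancer arrays raised to that level, the fall of CRISP3 was 2.05 on the log2 scale, and its place among these genes rests on the measured value. This estimate, called here the bound, was added after seeing the data and carries no standard error. It stands below for the other named genes with a tissue mean no higher than the controls. The MYL1 call was lost without pair 9, 10 or 12 (log2 -1.94 to -1.96, adjusted p up to 0.0538) and in the fit without the patient block (adjusted p = 0.0673).

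**Figure D2:**
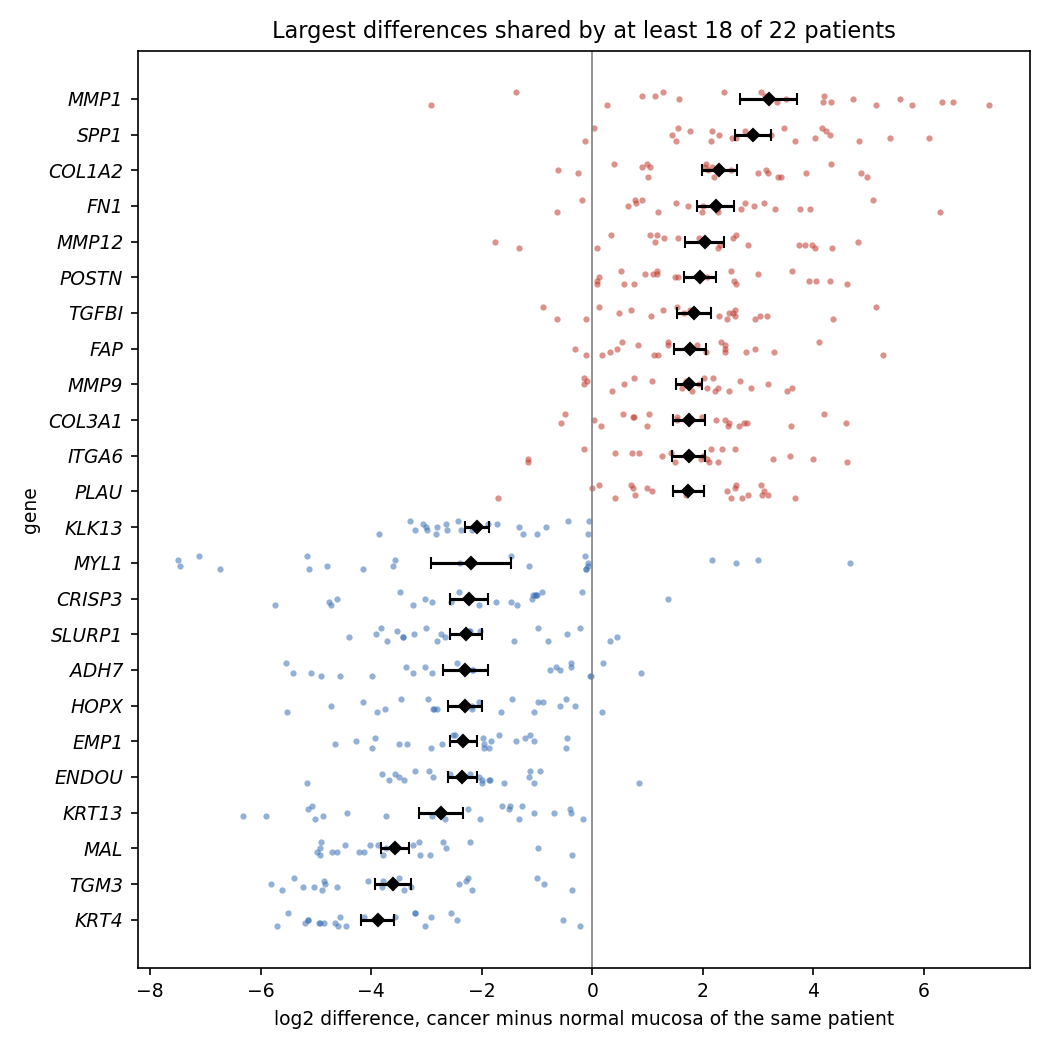
Log2 difference, cancer minus normal mucosa (horizontal axis), of the 12 genes with the largest rises and the 12 with the largest falls among those called and changed in that direction in at least 18 of 22 pairs (vertical axis). Each dot is 1 of 22 patients, and the diamond with its bar is the mean difference ± standard error of the paired fit. KRT4, TGM3, MAL and KRT13 lie below 0 in all 22 patients and POSTN lies above 0 in all 22.

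In total, 1715 probe sets (13.7% of those tested) were higher and 1418 (11.3%) were lower in cancer at an adjusted p under 0.05, by limma with the patient as a block. Of these, 82 were at least 2-fold higher and 125 at least 2-fold lower. The called probe sets with 1 gene named 1283 genes as higher and 1112 as lower, with 9 genes in both sets. Without the patient block 773 probe sets were higher and 599 lower, and all 1372 of them were also called with it. In the higher-control pairs 618 were higher and 504 lower, and in the lower-control pairs 386 and 387, with 347 called in both subsets, all of them in the same direction. Of the 1122 probe sets called in the higher-control pairs, 97.9% had the same sign in the other pairs, and 98.3% of the 773 called in the lower-control pairs did, against 71.7% of all probe sets. A score of skeletal muscle genes as a covariate left 984 higher and 913 lower.

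Of 26 gene lists fixed before the data were examined, 20 were called by camera at a preset correlation between genes of 0.01, 8 of them higher and 12 lower. None of the 20 calls held with an estimated correlation, where the smallest adjusted p was 0.0564. fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, called 18 lists. Of the 20 lists called by camera, 14 were called the same way in both subsets of pairs and 6 in 1 of them.

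**Figure D3:**
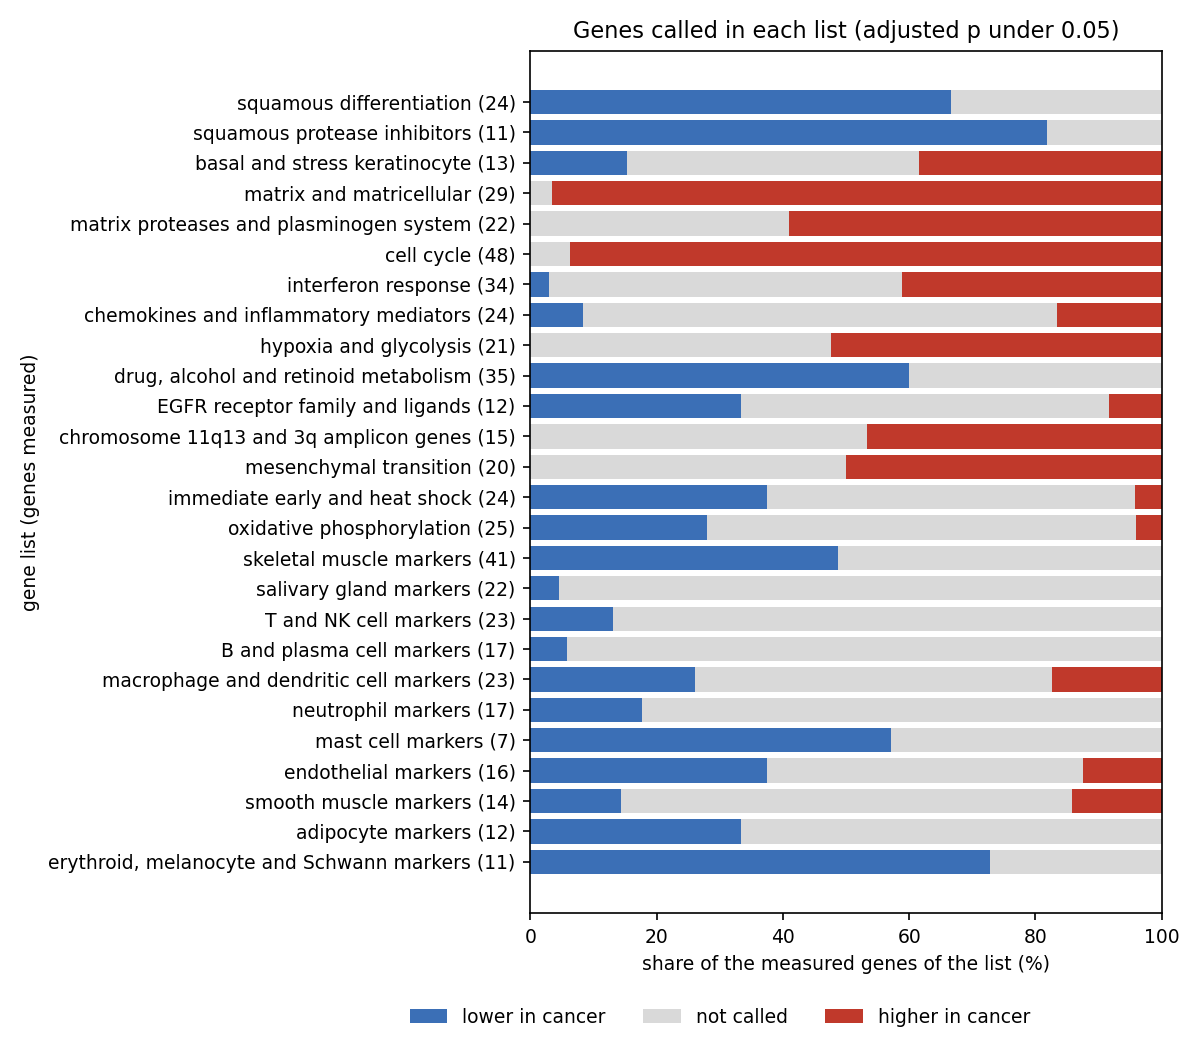
Share of each list's measured genes (horizontal axis, percent) called lower in cancer, not called, or called higher in cancer at an adjusted p under 0.05. The number in parentheses after each list (vertical axis) is the number of genes measured. In the matrix list 28 of 29 genes were higher, in the cell cycle list 45 of 48, and in the squamous differentiation list 16 of 24 were lower.

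Among squamous differentiation genes, 16 of 24 fell and 0 rose (18 lower when adjusted over the list alone), with a median of -1.25. The largest falls were those of KRT4, TGM3 and MAL, given above. The mean of the list fell from 9.74 ± 0.63 to 8.32 ± 0.69 log2 units (SD, n = 22) and was lower in 21 of 22 cancers. Camera called the list lower (adjusted p = 2.3e-13), with adjusted p = 0.0564 with an estimated correlation. In the list named squamous protease inhibitors, 9 of 11 genes fell (9 adjusted over the list alone; median -1.14). This list also holds genes that are not protease inhibitors, such as IL1RN and ANXA1. IL1RN, the interleukin 1 receptor antagonist, fell by 2.06 ± 0.39 on the log2 scale, the elastase inhibitor SERPINB1 by 1.63 ± 0.29, and cystatin CSTA by 1.52 ± 0.43. For this list camera gave adjusted p = 3.64e-05 and adjusted p = 0.257 with an estimated correlation. The medians in the higher-control and lower-control pairs were -1.07 and -1.26 for differentiation, and -1.01 and -1.08 for the inhibitor list. With the muscle score as a covariate 5 of these 11 genes were called lower, and CSTA was not (-1.20, adjusted p = 0.102). The salivary score as a covariate ended the CSTA call too (-1.32, adjusted p = 0.0646).

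Genes of the basal layer and of stressed keratinocytes went both ways: 5 of 13 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.33. KRT15, a keratin of resting basal cells, fell by 1.49 ± 0.27 on the log2 scale. ITGB4, the integrin subunit of hemidesmosomes, rose by 1.07 ± 0.23, and LAMB3, a chain of the laminin of the epithelial basement membrane, rose by 1.04 ± 0.23. ITGA6 rose by 1.02 ± 0.22 on the probe set of highest mean, and by 1.75 on the probe set of largest difference. The list was called higher by camera (adjusted p = 0.0451; adjusted p = 0.489 with an estimated correlation), and fry did not (adjusted p = 0.0714). The call was lost without any 1 of 12 pairs (pairs 1, 2, 3, 4, 5, 8, 13, 15, 16, 17, 18 and 21; medians of 0.26 to 0.35, adjusted p up to 0.129). The medians were 0.24 in the higher-control pairs (adjusted p = 0.0981) and 0.49 in the lower-control pairs (adjusted p = 0.0286).

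Of 29 matrix and matricellular genes, 28 rose in cancer and 0 fell (28 adjusted over the list alone), with a median of 1.23, led by COL1A2, FN1 and POSTN. Their mean rose from 7.61 ± 0.55 to 8.88 ± 0.71 log2 units (SD, n = 22) and was higher in 22 of 22 cancers. Of 22 matrix proteases and members of the plasminogen system, 13 rose and 0 fell (15 adjusted over the list alone), with a median of 0.62. MMP1, MMP12, a macrophage elastase, and MMP9, a gelatinase, led this list. Camera called both lists higher (adjusted p = 9.09e-21 and 8.01e-08), with adjusted p = 0.0638 and adjusted p = 0.0564 with an estimated correlation. The medians in the higher-control and lower-control pairs were 1.25 and 1.26 for the matrix list, and 0.46 and 0.70 for the proteases. Of 20 genes linked to mesenchymal transition, 10 rose and 0 fell (10 adjusted over the list alone), with a median of 0.15. PDPN, the membrane glycoprotein podoplanin, rose by 1.23 ± 0.22, the lectin LGALS1 by 1.18 ± 0.23, and the cadherin CDH3, a cell adhesion protein of basal epithelium, by 0.78 ± 0.22. Of 2 other PDPN probe sets, 1 was called higher and 1 was not called. CDH3 was not called with the salivary (0.66, adjusted p = 0.0754) or 3' to 5' (0.66, adjusted p = 0.0721) covariate. This list had a camera adjusted p = 0.000784 and adjusted p = 0.272 with an estimated correlation, and the medians in the subsets were 0.18 and 0.15.

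**Figure D4:**
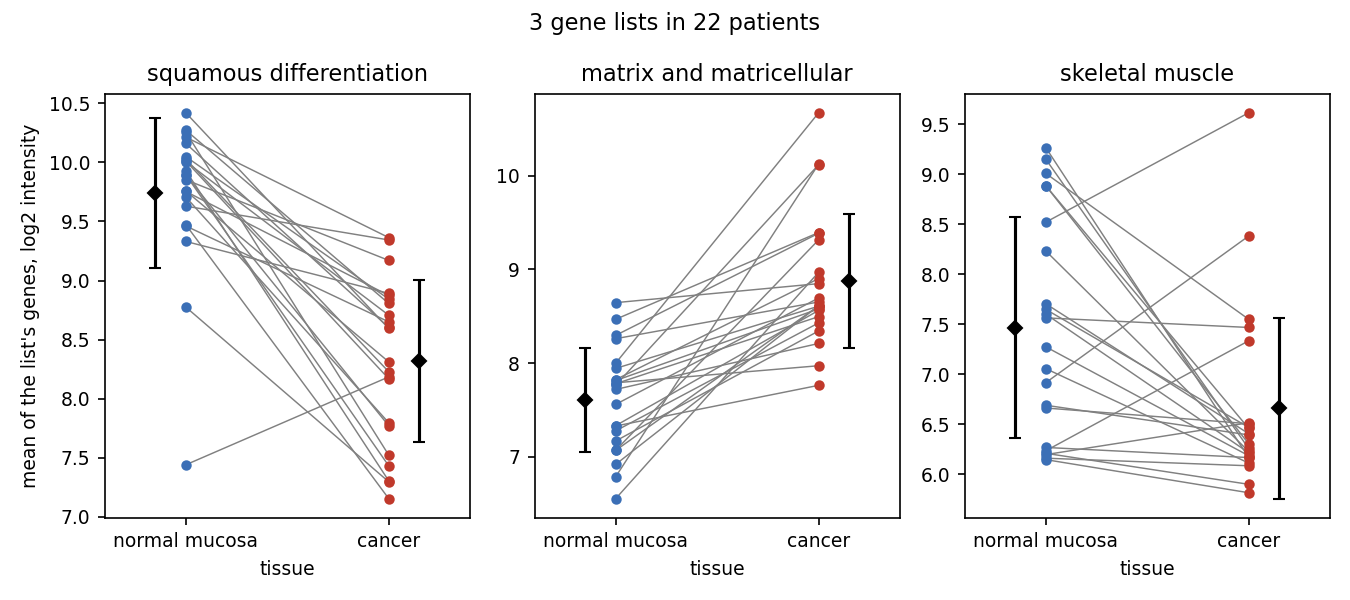
Mean log2 intensity of the genes of 3 lists (vertical axes) in normal mucosa and cancer (horizontal axes). Each point is 1 specimen, lines join the specimens of a patient, and diamonds with bars are the mean ± SD of 22 specimens. The matrix mean was higher in cancer in 22 of 22 patients, the differentiation mean lower in 21, and the skeletal muscle mean lower in 18 and higher in 4.

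Of 48 cell cycle genes, 45 rose and 0 fell (47 adjusted over the list alone), with a median of 0.50. The largest rises were those of RFC4, a subunit of the clamp loader of DNA replication (0.94 ± 0.12), CKS1B, a cyclin-dependent kinase subunit (0.92 ± 0.14), and UBE2C, a ubiquitin-conjugating enzyme of mitosis (0.81 ± 0.11). Camera gave adjusted p = 6.99e-27 and adjusted p = 0.0564 with an estimated correlation, and the medians were 0.56 and 0.47 in the higher-control and lower-control pairs. Of 21 hypoxia and glycolysis genes, 11 rose and 0 fell (11 adjusted over the list alone; median 0.25). P4HA2 and P4HA1, subunits of collagen prolyl hydroxylase, rose by 1.09 ± 0.19 and 0.78 ± 0.13, and ADM, which encodes the peptide adrenomedullin, by 0.61 ± 0.20. The ADM call was lost without pair 10 or 21 (0.56 and 0.54) and without the block (adjusted p = 0.0729). It was also lost with the muscle (0.44), salivary (0.54) or 3' to 5' (0.47) covariate (adjusted p of 0.195, 0.107 and 0.147). For these genes camera gave adjusted p = 5.28e-05 and adjusted p = 0.245 with an estimated correlation, with medians of 0.30 and 0.20 in the subsets. Without the patient block 5 of these 21 genes were called higher, and with the muscle score as a covariate 4 were.

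Of 15 genes in the regions of chromosomes 11q13 and 3q that are often amplified in this cancer, 7 rose and 0 fell (7 adjusted over the list alone; median 0.20). TFRC, the transferrin receptor, rose by 0.95 ± 0.24, PPFIA1, a liprin, by 0.43 ± 0.10, and FADD, a death receptor adaptor, by 0.39 ± 0.11. Camera gave adjusted p = 0.0122 and adjusted p = 0.272 with an estimated correlation, and medians in the subsets were 0.20 and 0.22. Without the block 4 of the 15 were called, and with the muscle score as a covariate 3 were, TFRC no longer among them (0.74, adjusted p = 0.0677). TFRC was not called with the 3' to 5' ratio as a covariate either (0.69, adjusted p = 0.0565). In the EGFR family, 1 of 12 receptors and ligands rose and 4 fell (2 and 5 adjusted over the list alone; median -0.12). EGFR rose by 0.75 ± 0.25, and the ligand HBEGF and the receptor ERBB2 fell by 0.58 ± 0.14 and 0.57 ± 0.08 on the log2 scale. Of 2 other ERBB2 probe sets, 1 was called lower and 1 was not called. EGFR was not called without the block (adjusted p = 0.0606), with the muscle score as a covariate (0.69, adjusted p = 0.111) or with the 3' to 5' ratio as a covariate (0.50, adjusted p = 0.1915). Camera did not call the list (adjusted p = 0.056; adjusted p = 0.306 with an estimated correlation), and fry did (adjusted p = 0.00216). Camera called it without pair 2, 3, 5, 6, 16 or 18 (medians of -0.13 to -0.11, adjusted p of 0.0431 to 0.0489), and the medians in the subsets were -0.05 and -0.18. Without the block 2 of the 12 genes were called lower and 0 higher.

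Of 35 genes of drug, alcohol and retinoid metabolism, 21 fell and 0 rose (23 lower adjusted over the list alone), with a median of -0.55 that was below 0 in 22 of 22 pairs. ADH7 fell as given above, the aldehyde dehydrogenase ALDH3A1 fell by 1.94 ± 0.40 on the log2 scale, and the secreted glutathione peroxidase GPX3 by 1.32 ± 0.15. Camera gave adjusted p = 1.33e-09 and adjusted p = 0.0564 with an estimated correlation, with medians of -0.45 and -0.56 in the subsets. Among immediate early and heat shock genes, 9 of 24 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.23). FOSB, a subunit of the AP-1 transcription factor, fell by 1.23 ± 0.21 on the log2 scale, and ZFP36, which destabilises messenger RNA, by 1.00 ± 0.14. NR4A1, a nuclear receptor, fell by 0.82 ± 0.29, but its call was lost without any 1 of 12 pairs (pairs 1, 5, 6, 7, 8, 9, 13, 14, 15, 16, 17 and 18; -0.83 to -0.68). Of 2 other NR4A1 probe sets, 1 was called lower and 1 was not called. The early genes had a camera adjusted p = 0.00113 and adjusted p = 0.334 with an estimated correlation, with medians of -0.32 and -0.25 in the subsets, and 3 of the 24 genes were called lower without the block.

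In oxidative phosphorylation, 7 of 25 genes fell and 1 rose (7 and 1 adjusted over the list alone; median -0.12). NDUFB5 of complex I rose by 0.38 ± 0.12, and UQCRC2 of complex III and ATP5F1A of the ATP synthase fell by 0.34 ± 0.09 and 0.34 ± 0.10 on the log2 scale. Camera called the list lower (adjusted p = 0.0248; adjusted p = 0.498 with an estimated correlation) and fry did not (adjusted p = 0.092). The call was lost without pair 7, 12 or 22 (medians of -0.13 to -0.10), without the block (adjusted p = 0.0689) and with the muscle score as a covariate (adjusted p = 0.213), and the last 2 settings called 0 of the 25 genes lower. The medians in the subsets were -0.13 and -0.16 (adjusted p = 0.0333 and 0.0521).

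Of 34 interferon response genes, 14 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.48. ISG15, a ubiquitin-like protein, rose by 1.30 ± 0.24, and BST2, the antiviral protein tetherin, by 0.95 ± 0.32. The chemokine CXCL11 differed by 0.85 ± 0.32 (adjusted p = 0.0553) and passed the threshold without pair 6 or 9 (0.97 and 0.93). It lay above the control level in 4 of 22 normal and 9 of 22 cancer arrays, and the bound was 0.30. BST2 lost its call without pair 4, 15, 16, 17 or 18 (0.79 to 0.88). The interferon list was called higher by camera (adjusted p = 3.79e-06; adjusted p = 0.39 with an estimated correlation). Its median was 0.15 in the higher-control pairs, where it was not called (adjusted p = 0.181), and 0.68 in the lower-control pairs (adjusted p = 3.81e-13), and the difference between these subsets was not tested. Without the patient block 4 of the 34 genes were called higher and 0 lower, and with the muscle score as a covariate 12 and 0. Among chemokines and inflammatory mediators, 4 of 24 rose and 2 fell (4 and 2 adjusted over the list alone; median 0.20). SPP1 rose as given above, the neutrophil attractant CXCL8 rose by 1.22 ± 0.30, and the monocyte attractant CCL2 fell by 1.25 ± 0.28 on the log2 scale. In the lower-control pairs CCL2 differed by -0.44 (adjusted p = 0.399) and was not called. Camera did not call this list (adjusted p = 0.0659; adjusted p = 0.498 with an estimated correlation), but did without pair 5, 6, 9 or 11 (0.23 to 0.26), and its medians were 0.17 and 0.33 in the subsets. Without the block 3 of its genes were called higher and 1 lower.

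The lists of immune cell markers had medians between -0.17 and 0.03. Of 23 T and NK cell markers, 3 fell (2 adjusted over the list alone; median -0.11). PRF1, the pore-forming protein perforin, fell by 0.29 ± 0.05 on the log2 scale and the granzyme GZMK by 0.35 ± 0.12, while the interleukin 7 receptor gene IL7R differed by 0.28 ± 0.17 (adjusted p = 0.247). GZMK lost its call without pair 3, 5, 6, 9, 10 or 11 (-0.33 to -0.29), and IL7R passed the threshold without pair 11 (0.40). Camera called the list lower (adjusted p = 0.0397; adjusted p = 0.546 with an estimated correlation), fry did not (adjusted p = 0.153), and the call was lost without pair 3, 5, 6, 9, 11, 13 or 20 (medians of -0.11 to -0.05). Its median was -0.22 in the higher-control pairs and 0.0015 in the lower-control pairs (adjusted p = 0.731), a difference that was not tested. Without the block 1 of the 23 genes was called lower, and 1 was with the muscle score as a covariate. Of 17 B and plasma cell markers, 1 fell (1 adjusted over the list alone; median -0.08): BLNK, a B cell linker protein, by 1.36 ± 0.17 on the log2 scale. JCHAIN, the joining chain of antibodies, differed by -0.996 ± 0.475 (adjusted p = 0.13) and IGLC1, an antibody light chain whose probe set shares sequence with related genes, by 0.31 ± 0.57 (adjusted p = 0.737). Camera did not call this list (adjusted p = 0.139; adjusted p = 0.629 with an estimated correlation), but did without pair 19 (-0.16), and its medians were -0.26 (adjusted p = 0.000402) and 0.07 in the subsets. Without pair 3, 5, 6 or 11 the median was -0.0507, -0.0316, -0.0306 and -0.0112.

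Of 23 macrophage and dendritic cell markers, 4 rose and 6 fell (6 and 7 adjusted over the list alone). FCER1A, an IgE receptor chain of dendritic and mast cells, fell by 0.94 ± 0.18 on the log2 scale, and the Fc receptor FCGR2A rose by 0.45 ± 0.14. C1QB, a chain of complement C1q, differed by 0.50 ± 0.21 (adjusted p = 0.082) and passed the threshold without pair 5 or 6 (0.60 and 0.61). The median and the mean of this list lay at 0.03 while camera pointed lower, with no call (adjusted p = 0.846; adjusted p = 0.93 with an estimated correlation), and its medians were 0.01 and 0.11 in the subsets. The median was 0.0218, 0.0135 and 0.0152 without pair 1, 14 or 18, and 0.0700, 0.0543 and 0.0668 without pair 5, 6 or 20. Camera pointed higher without pair 5, 6, 9 or 11 (medians of 0.0382 to 0.0700), with no call. Without the block 0 of these genes were called higher and 2 lower, with the muscle score as a covariate 2 and 5, and without pairs 11 and 21, which had a high actin ratio, 2 and 5. Of 17 neutrophil markers, 3 fell (3 adjusted over the list alone; median -0.12). These were LCN2, an iron-binding lipocalin (-1.21 ± 0.40), and S100A9 and S100A8, the subunits of calprotectin (-1.15 ± 0.36 and -1.07 ± 0.31), all of which squamous epithelium also makes. LCN2 lost its call without pair 7, 15 or 22 (-1.09 to -1.05), and with the muscle score as a covariate 0 of the 17 were called. Camera did not call the list (adjusted p = 0.202; adjusted p = 0.528 with an estimated correlation), with medians of -0.09 and -0.04 in the subsets and -0.0702 without pair 22. Of 7 mast cell markers, 4 fell (5 adjusted over the list alone; median -0.17). The proteases CTSG and CMA1 fell by 0.42 ± 0.14 and 0.25 ± 0.07 on the log2 scale, and HDC, the histamine-forming enzyme, by 0.25 ± 0.08, a call lost without pair 2 or 9 (-0.21 and -0.22). In the lower-control pairs HDC differed by -0.033 (adjusted p = 0.832). Camera gave adjusted p = 0.0122 for the mast cell list and adjusted p = 0.315 with an estimated correlation, with medians of -0.15 and -0.17 in the subsets, and 1 of the 7 was called without the block and 2 with the muscle score as a covariate.

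Of 41 skeletal muscle markers, 20 fell and 0 rose (23 lower adjusted over the list alone), with a median of -0.61 and a wide spread between patients. ACTA1, the actin of skeletal muscle, fell by 2.63 ± 0.78 on the log2 scale, MYL1 by 2.20 ± 0.72, and the oxygen carrier MB, myoglobin, by 1.97 ± 0.52. The standard deviation of ACTA1 over the specimens was 3.00 in normal mucosa and 2.69 in cancer, and ACTA1 was lower in cancer in 16 pairs and higher in 6. The muscle list was called lower by camera (adjusted p = 4.12e-07; adjusted p = 0.39 with an estimated correlation), and its medians were -0.72 and -0.48 in the subsets. Without the block 7 of the 41 genes were called lower, and 9 were without pairs 11 and 21, which held an array with a log2 actin 3' to 5' ratio above 1 (a choice made after seeing the data). Of 22 salivary gland markers, 1 fell (0 adjusted over the list alone; median -0.38). For STATH, the salivary protein statherin, the bound was -1.21 on the log2 scale. STATH lay above the control level in 11 of 22 normal and 4 of 22 cancer arrays. Its measured difference was -1.79 ± 0.59, a call lost without pair 1, 2, 3, 7, 10 or 16 (-1.67 to -1.53) and without pairs 11 and 21 together (-1.72, adjusted p = 0.0515). PRR4, a proline-rich salivary protein, differed by -1.48 ± 0.69 (adjusted p = 0.124) and AZGP1, a secreted glycoprotein, by -1.15 ± 0.46 (adjusted p = 0.0722), and both passed the threshold without pair 13 or 19 (-1.85 and -1.80 for PRR4, -1.32 and -1.30 for AZGP1). With the muscle score as a covariate 0 of the 22 genes were called. PRR4 differed by 0.0492 (adjusted p = 0.953) with the salivary score, of which it is part, as a covariate. Camera called the salivary list lower (adjusted p = 0.00167; adjusted p = 0.403 with an estimated correlation), with medians of -0.43 and -0.26 in the subsets.

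Of 16 endothelial markers, 6 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.09). CD34, a sialomucin of vessels, fell by 0.46 ± 0.07 on the log2 scale, the clotting factor VWF by 0.56 ± 0.17, and the adhesion receptor SELE by 0.68 ± 0.24. The SELE call was lost without any 1 of 12 pairs (pairs 1, 2, 5, 6, 7, 9, 11, 12, 13, 14, 15 and 22; -0.70 to -0.54). SELE differed by -1.13 (adjusted p = 0.0825) in the higher-control and -0.23 (adjusted p = 0.537) in the lower-control pairs. The VWF call was lost without the block (adjusted p = 0.0910) and with the muscle (-0.45), salivary (-0.52) or 3' to 5' (-0.39) covariate (adjusted p of 0.132, 0.0766 and 0.145). Without the block 3 of the 16 genes were called lower and 0 higher, with the muscle score as a covariate 4 and 0, and without pairs 11 and 21 5 and 1. The endothelial list was called lower by camera (adjusted p = 0.031; adjusted p = 0.403 with an estimated correlation), not so without pair 1, 5 or 13 (-0.08 to -0.07), and its medians were -0.08 and -0.10 in the subsets. Of 14 smooth muscle markers, 2 rose and 2 fell (3 and 4 adjusted over the list alone; median -0.12). The tropomyosin TPM1 rose by 1.32 ± 0.24, the smooth muscle myosin MYH11 fell by 1.07 ± 0.27 on the log2 scale, and SYNM, which encodes the filament protein synemin, differed by -0.64 ± 0.25 (adjusted p = 0.0597) and passed without pair 4, 13 or 19 (-0.75 to -0.73). Camera did not call this list (adjusted p = 0.586; adjusted p = 0.847 with an estimated correlation), with medians of -0.01 and -0.27 in the subsets. Single pairs moved its median widely, to above 0 without pair 1, 16 or 18 (0.0114, 0.00168 and 0.00711), to -0.0781 and -0.0602 without pair 2 or 11, and to -0.212 and -0.184 without pair 4 or 22. Without the block 1 of the 14 genes was called higher and 2 lower, as with the muscle score as a covariate.

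Of 12 adipocyte markers, 4 fell (5 adjusted over the list alone; median -0.24). CFD, the complement protease adipsin, fell by 1.10 ± 0.30 on the log2 scale and PLIN1, which coats lipid droplets, by 0.80 ± 0.23. ADIPOQ, the hormone adiponectin, differed by -1.05 ± 0.39 (adjusted p = 0.0501) on one probe set, was called on its other, and passed the threshold without pair 1, 4, 13 or 19 (-1.24 to -1.11). On the first of these it lay above the control level in 11 of 22 normal and 4 of 22 cancer arrays, and the bound was -0.50. Camera called the list lower (adjusted p = 0.0122; adjusted p = 0.334 with an estimated correlation), with medians of -0.20 and -0.31 in the subsets, and with the muscle score as a covariate 1 of the 12 was called. Of 11 markers of red cells, melanocytes and Schwann cells, 8 fell (9 adjusted over the list alone; median -0.28). The globin HBB, whose probe set shares sequence with related globins, fell by 1.05 ± 0.22 on the log2 scale, and the pigment cell gene PMEL by 0.49 ± 0.11. TYRP1, another such gene, had a measured difference of -0.57 ± 0.17 and a bound of -0.23. It lay above the control level in 10 of 22 normal and 3 of 22 cancer arrays. Camera gave adjusted p = 6.74e-06 and adjusted p = 0.0564 with an estimated correlation, with medians of -0.20 and -0.38 in the subsets.

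Of the signs of RNA quality, the log2 ratio of 3' to 5' beta-actin signal was 0.371 ± 0.476 in normal mucosa and 0.186 ± 0.413 in cancer (SD, n = 22). The difference of -0.185 did not pass adjustment over 9 control measures (permutation p = 0.0451, adjusted p = 0.0929, lower in 15 of 22 pairs). The same ratio of GAPDH differed by -0.129 (adjusted p = 0.0929, lower in 16 of 22 pairs). Leaving out the 2 pairs with a high actin ratio gave 1538 probe sets higher in cancer and 1307 probe sets lower in cancer, and 16 of 24 differentiation genes, 27 of 29 matrix genes and 45 of 48 cell cycle genes called in the directions given above.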

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

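The tests in this part were chosen after the main comparison had been seen. Control probe sets of the array lay outside the comparison of tissues, and 3 of 9 summaries of them were higher in cancer than in normal mucosa. The signal of the 18S ribosomal RNA probe sets was 0.24 ± 0.403 (SD, n = 22 pairs) log2 units higher in cancer, in 17 of 22 pairs (sign-flip permutation test, adjusted p = 0.0145). The transferrin receptor control probe sets were 0.821 ± 0.979 higher, in 17 of 22 pairs (permutation adjusted p = 0.00243), and the TFRC probe set of the main comparison differed by 0.95. The probe set for the middle of GAPDH, an enzyme of glycolysis, was 0.333 ± 0.475 higher, in 20 of 22 pairs (permutation adjusted p = 0.0145). These 3 differences kept their direction with quantile normalization (0.246, 0.825 and 0.354) and with array medians subtracted (0.244, 0.824 and 0.337). The other 6 summaries did not pass, among them the hybridization spikes (-0.107, adjusted p = 0.271) and the middle of beta-actin (0.16, adjusted p = 0.109).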

How the results depend on the processing

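The subsets of 11 pairs and the removal of pairs 11 and 21 were chosen after seeing the data. Over 19 alternatives, 63 of 76 values of the 4 counts of probe sets lay within 1.5 times the main count. Of 468 list results under 18 alternatives 403 kept the direction of camera and their side of the threshold, 47 lost a call, 8 gained one, and in 10 the direction of camera turned. Of 1685 results of named genes 1517 kept their sign and side of the threshold, 160 lost a call, 7 gained one and 1 turned. The last was PRR4 with the salivary covariate (0.0492, adjusted p = 0.953), called in neither fit. PRR4 is part of that covariate, so its loss of size came by construction. The median difference of all probe sets lay between -0.0142 and 0.00676 over the settings. Dim signals limit the 2-fold counts, which an offset of 64 lowered to 43 higher and 73 lower by its own construction. Unless a reason is given, the cause was not tested.

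Without the patient block, 773 probe sets were higher and 599 lower, and the calls of oxidative phosphorylation (median -0.12) and T and NK cell markers (-0.11) were lost. The random block lost the calls of these lists too (-0.12 and -0.11). No other list call changed in either fit. Array weights ended the T and NK call (-0.0452) and median subtraction the basal one (0.33). The milder filter on dim probe sets lost the basal (0.33), mast cell (-0.17) and endothelial (-0.0816) lists. Dropping the dimmest 50% left 1119 probe sets higher and 868 lower, since fewer were tested, and lost the basal (0.38), T and NK (-0.0723), mast cell (-0.25) and adipocyte (-0.22) lists. A floor of 20 lost the basal list (0.33).

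The macrophage and dendritic cell list, called in none of these fits, had a median above 0 while camera pointed lower. Camera pointed higher with array weights (median 0.0547), with the filters on dim probe sets (0.0587 and 0.0826), with the muscle (0.0618) and 3' to 5' (0.0408) covariates, and in the lower-control pairs (0.106). For smooth muscle, also uncalled, camera pointed higher with the muscle (-0.0773) and salivary (0.149) covariates. The median of the B cell list changed sign, though camera did not, with the muscle covariate (0.0165) and in the lower-control pairs (0.0725).

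The muscle covariate left 984 probe sets higher and 913 lower. It brought the median of the muscle list near 0 by construction (-0.0232, adjusted p = 0.985), where camera pointed higher although the median stayed below 0. It lost oxidative phosphorylation (-0.10), T and NK (-0.0410) and adipocyte (-0.14) lists, and gained the chemokine list (0.30). The salivary covariate lost its own list, by construction (-0.00918), and the T and NK list (-0.0930). The 3' to 5' covariate lost the basal (0.30) and endothelial (-0.0238) lists and gained the chemokine (0.28), EGFR family (-0.10) and B cell (-0.12) lists.

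The estimated correlation called 0 lists and left the medians as they were: differentiation -1.25, protease inhibitors -1.14, basal 0.33, matrix 1.23, matrix proteases 0.62, cell cycle 0.50, interferon 0.48, hypoxia 0.25, drug metabolism -0.55, amplicon genes 0.20, mesenchymal transition 0.15, immediate early -0.23, oxidative phosphorylation -0.12, skeletal muscle -0.61, salivary gland -0.38, T and NK -0.11, mast cell -0.17, endothelial -0.0911, adipocyte -0.24, and red cell, melanocyte and Schwann -0.28.

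The 11 higher-control pairs gave 618 higher and 504 lower probe sets, from fewer samples. They lost the basal (0.24), interferon (0.15) and adipocyte (-0.20) lists and gained the B cell list (-0.26). The 11 lower-control pairs gave 386 and 387, with 53 at least 2-fold higher. In the T and NK list the median and camera turned there (0.0015, adjusted p = 0.731), oxidative phosphorylation (-0.16) and endothelial (-0.10) lists were lost, and the chemokine (0.33) and EGFR family (-0.18) lists gained. Without pairs 11 and 21 the chemokine list was called (0.20) and the T and NK list was not (-0.0506).

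Of the named genes, 15 lost their call without the block: MYL1, BST2, ADM, EGFR, NR4A1, NDUFB5, UQCRC2, ATP5F1A, GZMK, FCGR2A, CMA1, HDC, SELE, VWF and HBB. With the muscle covariate 21 did: MYL1, CSTA, ADM, EGFR, TFRC, NR4A1, NDUFB5, UQCRC2, ATP5F1A, ACTA1, MB, STATH, GZMK, LCN2, S100A9, S100A8, CTSG, HDC, SELE, VWF and PLIN1. The salivary covariate ended 22 calls, of MYL1, CSTA, BST2, CXCL8, ADM, FADD, CDH3, NR4A1, NDUFB5, ACTA1, STATH, GZMK, FCGR2A, LCN2, S100A9, S100A8, CTSG, HDC, SELE, VWF, MYH11 and PLIN1. MYL1, ACTA1 and MB are part of the muscle score and STATH of the salivary score. Their losses with their own score came by construction. The 3' to 5' covariate ended 15, of MYL1, ADM, EGFR, TFRC, CDH3, NR4A1, NDUFB5, GZMK, FCGR2A, CTSG, HDC, SELE, VWF, CFD and TYRP1. From fewer samples, 27 were lost in the higher-control pairs and 41 in the lower-control pairs, and 4 without pairs 11 and 21 (MYL1, STATH, GZMK and SELE). Other settings ended calls of NDUFB5 and GZMK (random block), STATH and GZMK (array weights), SELE (quantile normalization), MYL1, NR4A1 and SELE (offset of 64), NR4A1 and SELE (floor of 20 and paired t-test) and NR4A1, SELE and TYRP1 (Wilcoxon test). AZGP1, SYNM and ADIPOQ gained a call with the random block, CXCL11 and C1QB with array weights, and ADIPOQ with the Wilcoxon test and with 1 probe set per gene.

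Leaving out 1 pair at a time kept the counts within 1.5 times: 1541 to 1721 higher, 1243 to 1473 lower, 64 to 91 at least 2-fold higher, 113 to 146 at least 2-fold lower, and 17 to 21 lists called. Lists whose call changed in some of these fits had medians of 0.26 to 0.45 (basal), 0.14 to 0.26 (chemokines), -0.135 to -0.0910 (EGFR family), -0.15 to -0.10 (oxidative phosphorylation), -0.123 to -0.0457 (T and NK), -0.160 to -0.0112 (B cells) and -0.117 to -0.0685 (endothelial). The macrophage list had medians of 0.0135 to 0.0700, with camera pointing higher without pair 5, 6, 9 or 11. The pairs that decided each call are named in the comparison.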

Other observations

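In this part, the gene families, the bacterial control test, the RNA degradation test of the first component and the epithelial marker test were chosen after related results had been seen. Several families share genes with the fixed lists, so they are not separate observations. Examples are MCM4, MCM6 and MCM7 (cell cycle), COL1A2 and COL3A1 (matrix) and LAMB3 (basal). Others are ALDH3A1 and CYP2J2 (drug metabolism) and KRT4 and KRT13 (differentiation). Among 28 gene families defined by symbol, subunits of the proteasome, which degrades tagged proteins, rose in 21 of 30 genes and fell in 0, with a median of 0.32 (camera adjusted p = 2.83e-09). PSMB2 (0.68), PSMD2 (0.57) and PSMD14 (0.53) rose most. Of the 6 minichromosome maintenance genes, which form the helicase of DNA replication, 6 rose (MCM4 by 0.58, MCM7 by 0.56 and MCM6 by 0.54; adjusted p = 3.3e-05). Of 8 subunits of the CCT chaperonin, which folds actin and tubulin, 6 rose and 1 fell (CCT5 by 0.57, CCT3 by 0.50; adjusted p = 0.0035). Of 18 HOX genes, which set position along the body axis, 4 rose and 0 fell (HOXB7 by 0.53; adjusted p = 0.0122). Collagens rose in 17 of 29 genes and fell in 2 (adjusted p = 1.43e-06), and laminins rose in 5 of 9 and fell in 1 (adjusted p = 0.0442). These 6 families kept their direction and call with quantile normalization and with array medians subtracted, though quantile normalization called 1 proteasome gene lower. With an estimated correlation none of the 28 families was called, and the smallest adjusted p was 0.168.

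Aldehyde dehydrogenases fell in 8 of 15 genes and rose in 1 (ALDH3A1 -1.94, ALDH3A2 -0.835; adjusted p = 0.000137). Of 28 cytochrome P450 genes 9 fell and 0 rose (CYP2J2 -0.71; adjusted p = 0.00648). Claudins, which seal tight junctions, fell in 4 of 9 (CLDN10 -1.43, CLDN7 -1.07; adjusted p = 0.00648), and tissue kallikreins in 3 of 9 (KLK13 -2.09, KLK11 -1.89; adjusted p = 0.0035). Of 26 keratins 10 fell and 0 rose (adjusted p = 0.0226). Cytosolic ribosomal proteins fell in 11 of 47 with a median of -0.09 (RPL14 -0.52; adjusted p = 0.0035), a call lost with quantile normalization (-0.05, adjusted p = 0.0660). The other 5 of these 6 families kept their direction and call under both scalings. The 3 genes of largest difference were looked at in each family. Families not called were serpins (2 higher, 5 lower of 24), S100 proteins (0 and 3 of 15), integrins (9 and 4 of 24) and HLA genes (3 and 0 of 15), among others.

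The first component was shared by the specimens of a patient. Array processing that differed between pairs is a candidate explanation: pair means of the component followed the bacterial control level at r = 0.876 (interval 0.721 to 0.948). Differing RNA degradation could not be settled, with r = -0.337 for the 3' to 5' ratio (interval -0.664 to 0.0989, permutation p = 0.125, rho = -0.431, permutation p = 0.0466). The interval leaves out a size above 0.7, a cut chosen after related results had been seen, but reaches -0.664. Within the higher-control pairs that r was -0.848 and within the lower-control pairs 0.43, so a part in some pairs stays open. Differences between the patients themselves stay open too and were not tested.

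Skeletal muscle genes fell in cancer with a wide spread. The muscle score was lower in cancer in 16 pairs and higher in 6. RNA degradation in the normal specimens had been set out as an explanation, though it would lower muscle genes there and not in cancer. The pair differences in the muscle score and the 3' to 5' ratio had r = -0.0138 (interval -0.433 to 0.41). This value argued against differing degradation within pairs, in either tissue, as the main source. That r was 0.369 in the higher-control and -0.343 in the lower-control pairs, so a part in some pairs stays open. Without pairs 11 and 21 9 of the 41 genes were called in place of 20 (list median -0.52, still called by camera). The array with the actin ratio above 1 was the cancer one in pair 11 (1.26) and the normal one in pair 21 (1.80). In pair 21 the muscle score was -0.673 in normal mucosa and -1.02 in cancer. In pair 11 it was 1.30 in normal mucosa and -0.339 in cancer, so its large fall came with a high cancer ratio. The loss of calls therefore says little about degradation in the normal specimens. Degradation in the cancer specimens cannot be judged from 1 such pair. Differing amounts of muscle fibres in the specimens, from sampling or from tissue replaced by cancer, stay open and were not tested, as does a change in muscle gene regulation.

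The fall of squamous differentiation genes (median -1.25) was set against less epithelium in the cancer specimens. The median of 26 epithelial markers, not all of them junction or keratin genes and 11 also in the fixed lists, was -0.0315 (bootstrap interval over pairs -0.243 to 0.189). It lay above -0.627, a cut chosen for this test. Of these markers 5 rose (ITGB4 1.07, LAMB3 1.04, ITGA6 1.02, CDH3 0.78 and DSG2 0.56). Another 5 fell (KRT15 -1.49, KRT19 -1.24, DSG3 -0.87, OCLN -0.42 and ST14 -0.28). The interval does not cover the choice of markers, and rises of single markers in cancer could hide a loss of epithelium. So the markers as a set did not fall as the differentiation list did, but less epithelium is not excluded. A change of state of the epithelial cells in cancer stays open too and was not tested.

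Hypotheses on 5 relations between the changes of lists within pairs were written before their values were seen, and p-values were adjusted over the 5. Matrix and matrix protease changes may go together: r = 0.698 over 22 pairs (interval 0.391 to 0.865, permutation p = 0.00027, adjusted 0.00135) and rho = 0.526 (permutation p = 0.0139, adjusted 0.0232). Without the 2 farthest pairs r was 0.412, so part of the relation rests on them, and it was 0.485 and 0.855 in the higher-control and lower-control pairs. Interferon changes and those of T and NK cell markers had r = 0.671 (permutation p = 0.00074, adjusted 0.00185) and rho = 0.622 (permutation p = 0.00242, adjusted 0.00605), with 0.568 without the 2 farthest pairs and 0.637 and 0.597 in the subsets. Matrix and differentiation changes went in opposite directions, with r = -0.64 (permutation p = 0.00115, adjusted 0.00192) and rho = -0.637 (permutation p = 0.00189, adjusted 0.00605), -0.508 without the 2 farthest pairs, and -0.595 and -0.786 in the subsets. These 3 relations had the same sign in each subset, where they were not tested, and a shared shift in the mix of stroma and epithelium is open as a cause of the last relation.

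The other 2 relations could not be settled. Differentiation and cell cycle changes had r = -0.169 (interval -0.551 to 0.272, permutation p = 0.452, adjusted 0.452; rho = -0.185, permutation p = 0.408, adjusted 0.408), -0.338 without the 2 farthest pairs, and -0.409 and 0.0508 in the subsets. Hypoxia and cell cycle changes had r = 0.404 (interval -0.0207 to 0.706, permutation p = 0.0625, adjusted 0.0781), 0.313 without the 2 farthest pairs, and 0.191 and 0.484 in the subsets. Their rho of 0.494 passed (permutation p = 0.0206, adjusted 0.0258).

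Exchanging the tissue labels within randomly chosen pairs tested whether chance gives such counts. Of 100 relabellings with the real one included, 1 gave as many as the 1715 higher probe sets and 1 as many as the 1418 lower ones, and the highest other count was 1105. For at least 2-fold differences 2 of 100 reached the 82 higher probe sets and 1 the 125 lower ones, and the highest other was 89. Each count thus passed at 0.05 as a test of no tissue difference in any probe set. The relabellings do not give the share of false calls among the probe sets called. The relabelling with the highest other counts had kept 20 of 22 pairs in their real order, and 97 of the 99 others called 0 probe sets.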
